A study of Mus musculus with 6 samples.

How the data were processed

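Small RNA was sequenced from extracellular vesicles (EVs), the membrane particles that cells release, recovered from mouse brain. The labels give 2 groups of 3 libraries each, vesicles from mice that had gone through status epilepticus (SE-BDEV 1 to 3) and vesicles from matched controls (CON-BDEV 1 to 3). All titles carry day 10, and what the day is counted from is not given in the sources used here. Per the labels' protocols, RNA was purified with the miRNeasy Micro Kit with DNase and libraries were made with the QIAseq miRNA Library Kit. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

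The authors deposited a table of RPM values, reads scaled to the same total in each library, for 1926 miRNA features. Of these features 803 were above 0 in at least 1 library, 1123 were listed at 0 in all 6, and 35 rows merged mature miRNAs of similar name. The authors deposited a second table of their own comparison of 803 features, with a mean normalized signal, a log2 fold change with its standard error, a test score, p-values and adjusted p-values. The submitters' processing notes name DESeq2 and the mouse build mm9, without versions. The aligner and the counting tool are not given in the sources used here, nor is whether reads were collapsed by molecular identifier.

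In every library all RPM values were whole multiples, within a tolerance of 0.001 step, of a single step that was taken as 1 read. This gave 4400167, 8147118 and 6578279 reads for CON-BDEV 1, 2 and 3, and 9391887, 4996073 and 6749631 for SE-BDEV 1, 2 and 3. The reads divided by median-of-ratios size factors gave the mean normalized signal of the authors' deposited table with a largest relative difference of 1.39e-09. The authors' comparison therefore rested on these values, with the same zeros. The smallest listed value was 2 reads in every library, so a 0 stands for fewer reads than that or for a value set to 0 before that comparison. A count of 3 reads corresponded to 0.319 to 0.682 RPM, and such floors cover counting error only. Because no value of 1 read is listed, the values were not taken as a full count table and no count model was fitted. The authors' deposited DESeq2 table is the count-based result.

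The comparison used limma 3.58.1 in R 4.3.3 (with statmod 1.5.0) on log2(RPM + 1), with an intensity trend and robust empirical Bayes, two-sided, for the 308 miRNAs with a mean of 10 RPM or more over the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Fold changes are on the log2(RPM + 1) scale, which understates the change of low miRNAs, and their errors are the moderated standard errors. Group values are mean ± SD. Differences in single library measures were tested with an exact permutation test, whose smallest possible p for 3 against 3 is 0.1. A set of 17 miRNA lists with 259 members (cell types, blood, other organs, seizure-related sets, families and genomic clusters) was written before the values were examined. The 15 lists with 3 or more tested members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Hairpin GC content came from GENCODE M21 (GRCm38) and was available for 98.7% of tested miRNAs. That annotation is of another build than the submitters' notes name, so it was used for names, sequence composition and neighbouring genes, and no coordinates are given. Figures were drawn with matplotlib 3.10.9.

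The groups share replicate numbers, and the correlation of deviations from the group means was 0.216, 0.202 and 0.462 for the pairs numbered 1, 2 and 3. All 3 exceed the bound of 0.1 that had been set for treating the numbers as pairs, and nothing in the labels says that they are pairs. CON-BDEV 2 with SE-BDEV 1 (0.336) and CON-BDEV 1 with SE-BDEV 2 (0.200) exceeded it as well. Correlations of a library numbered 3 with one of another number were negative (-0.270 to -0.410). The bound thus does not mark out the pairs numbered 1 and 2. The same-number correlations rested on a single miRNA: without miR-24-3p, which was listed at 0 except in both libraries numbered 3, they were -0.06, -0.06 and -0.08. Values with the replicate number as a block are therefore given where they change a call, with this limit.

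The fit was tested on simulated data for SE-BDEV against CON-BDEV, with 803 miRNAs and 20 simulations at the libraries' own depths and spread. Of 200 simulated changes at each size, 37.5% were called at a log2 fold of 1, 98.0% at 2 and 100% at 3, and 8.01% of calls were false. In 3 of the 20 simulations without changes at least 1 miRNA was called. miRNAs listed at 0 in any library were simulated with the median spread, because the spread of miR-24-3p, if drawn as noise, distorted library totals. This was set after a first run without it had missed its bound for recovery. Noise was drawn independently for each miRNA, while the correlation estimated by camera within a list reached 0.724 in the data. Each simulation with changes also held all 3 sizes together. The larger changes ease the adjusted threshold for the smaller ones, so 37.5% may be too high where few miRNAs change. These rates may therefore not hold for the data.

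Named miRNAs followed a rule written before the data were examined: the 10 most abundant, up to 12 called in each direction with separated groups, those of smallest p up to 10 per direction, up to 4 members per list, and the 10 of smallest adjusted p in the authors' deposited table with a mean of 10 RPM or more. The alternatives were other pseudocounts, abundance filters, scalings, limma settings, array weights, the replicate block and leaving out each library. Added after seeing the data were the removal of a GC trend, restriction to miRNAs above 0 in all libraries, leaving out miR-24-3p, leaving out both libraries numbered 3, and the count of lists by fry in place of camera.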

Results

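The series profiled miRNAs in brain-derived EVs from mice after status epilepticus, a prolonged seizure, and from matched controls, with 3 libraries per group at day 10. Libraries held 4400167 to 9391887 reads assigned to miRNAs and between 532 and 631 miRNAs above 0. Mean depth did not differ between the groups by more than the spread between libraries (exact permutation p = 0.7, smallest possible 0.1).

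The let-7 family, abundant in mature brain, made up most of the vesicle miRNA in both groups. It accounted for 80.5% ± 1.26 of RPM in CON-BDEV and 78.8% ± 2.72 in SE-BDEV (SD, n = 3, exact permutation p = 0.4, smallest possible 0.1). let-7c-5p was the most abundant miRNA, at 33.9% ± 0.268 and 31.2% ± 2.65 (SD, n = 3, exact permutation p = 0.2). The 10 most abundant miRNAs were let-7c-5p, let-7b-5p, let-7a-5p, let-7f-5p, let-7d-5p, let-7g-5p, the merged let-7e-5p/7k, let-7i-5p, miR-26a-5p and miR-191-5p. The neuronal miR-124-3p stood at 8213 ± 800 RPM in CON-BDEV and 8061 ± 1444 RPM in SE-BDEV (SD, n = 3).

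Spearman correlations between libraries over the tested miRNAs ranged from 0.897 to 0.972. On the first principal component, with 42.5% of the variance, both libraries numbered 3 lay apart from the other 4. miR-24-3p was listed at 0 in those 4 and at 3544 RPM in CON-BDEV 3 and 3128 RPM in SE-BDEV 3. Without it the first component held 38.0% of the variance. CON-BDEV 1 lay farthest out at -11.22, with CON-BDEV 2 at -1.53 and CON-BDEV 3 at -0.0259. The 3 SE-BDEV libraries lay between 4.13 and 4.37, so the groups did not overlap on this component.

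**Figure D1:**
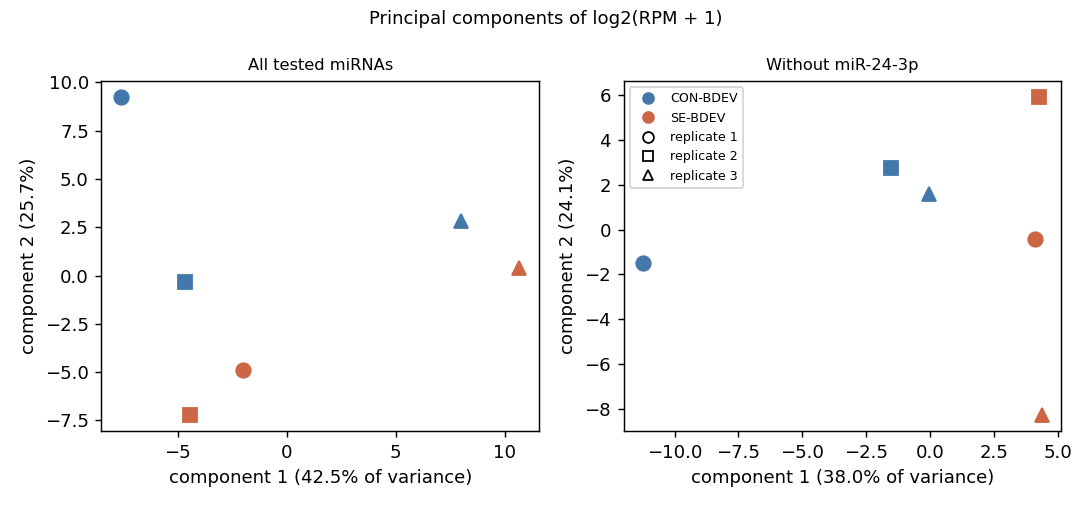
Scores of the 6 libraries on the first 2 principal components of log2(RPM + 1), with all tested miRNAs (left) and without miR-24-3p (right), where colour gives the group and marker the replicate number. In the left panel both libraries numbered 3 lie to the right at 8.01 and 10.68. In the right panel CON-BDEV 1 lies alone at -11.22. The 3 SE-BDEV libraries lie there at 4.13 to 4.37, above all CON-BDEV libraries.

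The comparison the design states is SE-BDEV against CON-BDEV. miR-155-5p, miR-21a-5p and miR-142a-5p were higher in the SE-BDEV libraries, and no miRNA was lower past the threshold. Since the labels do not say that the libraries of a group came from separate animals, the spread behind these p-values may be technical. miR-155-5p, an inflammation-induced miRNA of immune cells, went from 34.7 ± 6.15 to 222 ± 34.8 RPM (SD, n = 3), a log2 fold change of 2.65 ± 0.30 (SE, limma adjusted p = 0.000284). miR-21a-5p, which is raised in many settings of tissue injury, went from 15.1 ± 7.20 to 126 ± 33.2 RPM (SD, n = 3), a log2 fold change of 3.08 ± 0.40 (SE, limma adjusted p = 0.000498). miR-142a-5p, from a hairpin expressed in blood-forming lineages, went from 24.3 ± 3.00 to 92.7 ± 28.2 RPM (SD, n = 3), a log2 fold change of 1.85 ± 0.32 (SE, limma adjusted p = 0.00761). For each of them all 3 SE-BDEV values lay above all 3 CON-BDEV values. In GENCODE M21 (GRCm38) the miR-155 hairpin lies within an exon of Mir155hg, the miR-21a hairpin within an exon of Vmp1 and the miR-142 hairpin in an intron of Mir142hg.

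**Figure D2:**
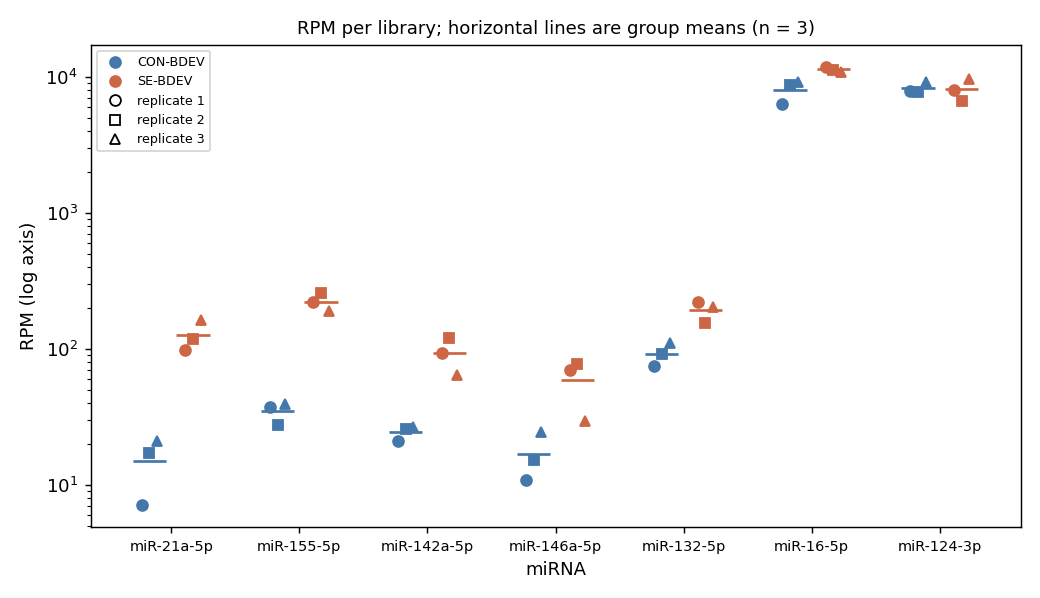
RPM (log axis) of 7 miRNAs in each of the 6 libraries, with group means as horizontal lines (n = 3). miR-155-5p, miR-21a-5p and miR-142a-5p are higher in every SE-BDEV library, while miR-124-3p overlaps between the groups.

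Below the called miRNAs, miR-146a-5p, a regulator of inflammatory signalling, was at 17.0 ± 7.0 RPM in CON-BDEV and 58.8 ± 25.9 RPM in SE-BDEV (SD, n = 3; log2 difference 1.69, limma adjusted p = 0.105). It passed with array weights (adjusted p = 0.0128), over miRNAs above 0 in all libraries (0.0431), without CON-BDEV 2 (0.0126), without SE-BDEV 3 (0.0193) and without both libraries numbered 3 (0.00646), and its adjusted p over 23 alternatives ranged from 9.34e-05 to 0.723. The other miRNAs of smallest p with higher values in SE-BDEV were miR-20a-5p (log2 difference 1.17), miR-132-5p (1.06), miR-15b-5p (0.89), miR-142a-3p (1.37), miR-6240 (1.05) and miR-872-5p, with limma adjusted p of 0.237 to 0.344. miR-872-5p was listed at 0 in CON-BDEV 1 and 2, at 13.7 RPM in CON-BDEV 3 and at 15.5 to 19.3 RPM in SE-BDEV. Those of smallest p with lower values were miR-935 (-0.90), miR-330-3p (-0.98), miR-328-3p (-0.96), miR-667-3p (-1.003), miR-3102-3p (-1.03), miR-383-5p (-0.67), let-7d-3p (-0.91), miR-744-5p (-0.91), miR-92b-3p (-0.86) and miR-1224-5p (-0.87), with limma adjusted p of 0.344 to 0.438.

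Of the 308 tested miRNAs, 32 had an unadjusted p under 0.05, 25 higher and 7 lower in SE-BDEV. This balance depended on the scaling: 57.5% of tested miRNAs had higher values in SE-BDEV, against 49.0% with median-of-ratios scaling, where the split was 16 higher and 19 lower. It was 46.8% (18 and 9) with the total taken without the 10 most abundant, 48.1% (19 and 17) with quantile normalization and 44.7% (21 and 17) with a GC trend removed. The split also moved with single libraries, from 34 higher and 4 lower without SE-BDEV 2 to 19 and 20 without CON-BDEV 2. With the replicate block it was 34 and 19. The groups did not overlap for 33 miRNAs higher and 17 lower, together 16.2% of the 308. Chance gives 10% for both directions together, or 30.8, and miRNAs are not independent replicates. With the replicate number as a block 10 miRNAs passed, 9 higher and 1 lower, adding miR-146a-5p (adjusted p = 9.34e-05), miR-132-5p (0.0487), miR-376c-3p (0.0411), miR-6240 (0.0435), miR-872-5p (0.00611), miR-7056-5p and miR-296-3p. The last 3 were listed at 0 in at least 1 library. With miRNAs above 0 in all libraries alone the blocked count was 4, and miR-132-5p, miR-376c-3p and miR-6240 lost their calls as well. The call of miR-142a-5p was lost without CON-BDEV 1 (adjusted p = 0.0759), SE-BDEV 1 (0.0931) or SE-BDEV 2 (0.0707), and 8 miRNAs passed without CON-BDEV 2.

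The authors' deposited table gave 7 miRNAs an adjusted p under 0.05, 5 higher and 2 lower in SE-BDEV. They included all 3 miRNAs called by limma, with deposited log2 fold changes of 2.64 for miR-155-5p, 2.97 for miR-21a-5p and 1.87 for miR-142a-5p. The authors' deposited table also held miR-132-5p, an activity-induced neuronal miRNA, at a log2 fold change of 0.98 (adjusted p = 0.00608) and miR-935 at -1.01 (adjusted p = 0.0117). The other 2, named after their values were seen, had a mean under 10 RPM. miR-6983-5p was listed at 0 in all CON-BDEV libraries and at 3.26 to 6.07 RPM in SE-BDEV, and miR-1247-5p was listed at 0 in all SE-BDEV libraries and at 1.10 to 13.4 RPM in CON-BDEV. Between 0.05 and 0.10 the authors' deposited table held miR-146a-5p (adjusted p = 0.0744), miR-328-3p (0.0832), miR-129-5p (0.0882), miR-20a-5p (0.0946) and miR-330-3p (0.0946) among those above the filter named by rule. Of the 308 tested miRNAs, 278 (90.3%) had the same sign in that table and in limma.

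In the list of microglial and inflammatory miRNAs all 7 tested members were higher in SE-BDEV, 3 passed over all miRNAs tested and 6 passed adjusted over the list alone, with a median log2 difference of 1.69 (camera adjusted p = 1.18e-08). With an estimated correlation the camera adjusted p = 0.098, and fry's directional test gave an adjusted p of 0.00585. Beside the called miRNAs and miR-146a-5p, the list held miR-142a-3p (log2 difference 1.37), miR-146b-5p (0.83) and miR-342-3p (0.11). With the block and an estimated correlation the adjusted p = 0.621, and without members shared with other lists it was 0.0808.

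The list of miRNAs raised after seizures in earlier work had 9 of 12 tested members higher, with 3 past the threshold over all miRNAs and 4 adjusted over the list alone (camera adjusted p = 0.000189, adjusted p = 0.426 with an estimated correlation). The members that passed were miR-155-5p, miR-21a-5p and miR-142a-5p, which the microglial list also holds. miR-132-3p and miR-212-3p had log2 differences of 0.71 and 0.80, and miR-134-5p of -0.30. The miR-17 family clusters, linked to cell proliferation, had all 5 tested members higher, none past the threshold over all miRNAs and 1, miR-20a-5p, adjusted over the list alone (camera adjusted p = 0.0375, adjusted p = 0.426 with an estimated correlation). This list lost its camera call with the block (adjusted p = 0.0708), a pseudocount of 10 (0.0688), a mean of 1 RPM or more (0.0864) or no filter (0.0709). It was also lost without SE-BDEV 1 (0.0784), CON-BDEV 2 (0.0775) or SE-BDEV 2 (0.0702), and in the run without shared members (0.0808), where its 5 tested members stayed. miR-93-5p had a log2 difference of 0.56.

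The other lists did not pass by camera in the main comparison, and 5 of them passed under some alternatives. With an estimated correlation the main adjusted p was 0.937 for the neuron and astrocyte lists, 0.578 for the endothelial, 0.689 for the choroid and 0.947 for the Dlk1-Dio3 list. Neuron-enriched miRNAs were higher for 15 of 18 (adjusted p = 0.153, or 0.0412 without CON-BDEV 3), with miR-129-5p at a log2 difference of 0.52. Astrocyte-associated miRNAs were higher for 7 of 9 (0.185, or 0.0412 without CON-BDEV 3), and the 1 past the threshold, also adjusted over the list alone, was miR-21a-5p. Endothelial and mural miRNAs were higher for all 6 (0.0933, or 0.0408 with quantile normalization, 0.0412 without CON-BDEV 3, 0.0427 without SE-BDEV 3 and 0.0186 without both), with miR-126a-5p at 0.72. Choroid plexus and ependymal miRNAs were higher for all 4 (0.185, or 0.0354 with no filter and 0.0400 without CON-BDEV 1), with miR-34c-5p at 0.81, and those of other organs for 3 of 4 (0.211), with the muscle miR-1a-3p at 0.83. Of the blood list 1 of 3 was higher (0.990), miR-16-5p at 0.51, while miR-451a and miR-144-3p were listed at 0 in all libraries. None of the members of the neuronal, vascular, choroid, organ and blood lists passed, over all miRNAs or adjusted over the list alone. By fry's mixed test, for change in either direction, 4 lists passed. They were the microglial list and the list raised after seizures (fry mixed adjusted p = 0.00109 for each), and the miR-17 and other organs lists (0.00381 for each).

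Among families and clusters, 19 of 39 tested miRNAs of the imprinted Dlk1-Dio3 cluster were higher and 20 lower (camera adjusted p = 0.232, or lower at 0.0400 without CON-BDEV 1 and 0.0375 without SE-BDEV 3), with miR-376c-3p at a log2 difference of 1.09 and miR-667-3p at -1.003. let-7 members were higher for 6 of 11 (0.985), miR-30 members for 6 of 8 (0.985), miR-181 members for 7 of 7 (0.788) and Sfmbt2 cluster members for 4 of 5 (0.703). miRNAs lowered after seizures in earlier work were higher for 5 of 7 (0.788), with miR-128-3p at 0.10. The let-7 and miR-30 medians were 0.10 and 0.04, while camera gave their direction as lower. No member of these 6 lists passed over all miRNAs or adjusted over the list alone. The oligodendrocyte list had 2 tested members, of which miR-338-3p had a log2 difference of 0.72, and the miR-200 list had 1, miR-429-3p at 0.38, so neither was tested as a set.

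**Figure D3:**
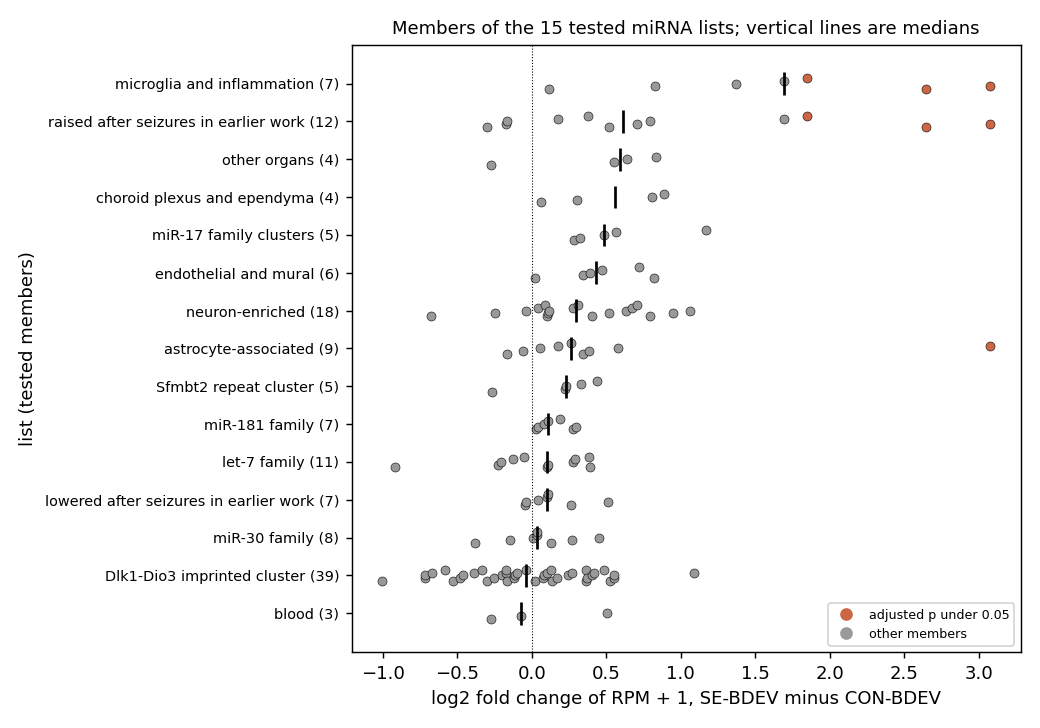
Log2 fold change of RPM + 1 (SE-BDEV minus CON-BDEV) of each tested member of 15 miRNA lists, with the number of members in brackets, list medians as vertical lines and members under an adjusted p of 0.05 coloured. The microglial and inflammatory list has the highest median, 1.69, and the blood list the lowest, -0.0748.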

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

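The removal of a GC trend, the restriction to miRNAs above 0 in all libraries, the runs without miR-24-3p or without both libraries numbered 3, and the count of lists by fry in place of camera were chosen after seeing the data. fry itself was planned beside camera. miR-155-5p passed under all 24 alternatives that tested it, with log2 fold changes of 2.35 to 2.85, and miR-21a-5p under all 23, with 2.46 to 3.36. miR-142a-5p passed under 19 of 23 (1.52 to 2.15, adjusted p from 1.47e-06 to 0.0931). It lost its call with the 10 most abundant miRNAs left out of the total (adjusted p = 0.0648) and without CON-BDEV 1, SE-BDEV 1 or SE-BDEV 2. At a mean of 100 RPM or more it and miR-21a-5p were not tested. These ranges leave out the runs with GC from the arm's side of the hairpin. There miR-155-5p was at 2.26, miR-21a-5p at 2.77 and miR-142a-5p at 1.46, and all passed.

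Against 3 called miRNAs, the count was 1 at a mean of 100 RPM or more, where 129 miRNAs were tested, 6 with array weights, 10 with the replicate block and 32 at an unadjusted p under 0.05. The block gave 10 without miR-24-3p as well, 7 with the GC trend removed (3 with GC from the arm's side of the hairpin), where let-7d-3p (adjusted p = 0.0408) and miR-382-5p were called lower, and 4 over miRNAs above 0 in all libraries. Leaving out 1 library gave 2 to 8, the 8 without CON-BDEV 2 being 4 higher and 4 lower. The authors' deposited table held 7 miRNAs at an adjusted p under 0.05, 15 under 0.10 and 52 at an unadjusted p under 0.05. Against 3 lists by camera, 1 passed at a mean of 100 RPM or more, 1 with fry's directional test, 0 with an estimated correlation and 0 without shared members. At 100 RPM or more the microglial and miR-17 lists had fewer than 3 members left and were not tested. Without shared members the same held for the list raised after seizures. Quantile normalization and the run without both libraries numbered 3 gave 4, adding the endothelial and mural list. Leaving out 1 library gave 2 to 6 lists, the added ones being the neuron, astrocyte, endothelial, choroid and Dlk1-Dio3 lists at the values in the report. With shared members left out, the adjusted p of the microglial and miR-17 lists was 0.0808, and the miR-17 list kept all 5 tested members, so its change came from the adjustment over lists. Without a GC correction, the block changed the calls of no miRNAs or camera lists but those named here and in the report. Where no construction explains a change, the cause was not tested.

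Some uncalled values changed sign. For miR-191-5p, miR-30d-5p and miR-181a-5p the log2 difference was -0.0689, -0.0332 and -0.0417 with median-of-ratios scaling. With the 10 most abundant left out of the total they were -0.0899, -0.0542 and -0.0627, with miR-181b-5p at -0.0111. With quantile normalization these 4 were -0.11, -0.15, -0.13 and -0.0448. With the GC trend removed, with or without the block, let-7a-5p was at -0.16, let-7f-5p -0.0838, let-7d-5p -0.14, miR-191-5p -0.0140, miR-30d-5p -0.0466, miR-181a-5p -0.23, miR-181b-5p -0.16, miR-669c-5p -0.19 and miR-466i-5p -0.14. Without both libraries numbered 3, miR-128-3p was at -0.0402, miR-30d-5p -0.0671 and miR-181a-5p -0.0924. Leaving out 1 library gave -0.0855 to 0.16 for miR-191-5p, -0.17 to 0.0925 for miR-124-3p, -0.14 to 0.34 for miR-128-3p, -0.13 to 0.29 for miR-30d-5p, -0.12 to 0.29 for miR-181a-5p and -0.0583 to 0.26 for miR-181b-5p.

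Among uncalled lists, the blood list turned lower with adjusted p of 0.938 (median-of-ratios), 0.981 (10 most abundant left out), 0.977 (quantile), 0.963 (replicate block), 0.998 and 0.965 (miRNAs above 0 in all libraries, without and with the block) and 0.961 (without miR-24-3p, with the block). The miR-30 list turned higher at 0.937 (mean of 1 RPM or more), 0.971 (no filter) and 0.915 (without both libraries numbered 3), the let-7 list at 0.777 (mean of 100 RPM or more) and 0.915 (without both libraries numbered 3). The list lowered after seizures turned lower at 0.971 (no filter) and 0.996 (without both libraries numbered 3), and the Sfmbt2 list at 0.267 and 0.309 (GC trend removed, without and with the block). Leaving out 1 library gave adjusted p of 0.741 to 1.000 for the blood list, 0.211 to 1.000 for the list lowered after seizures, 0.544 to 0.973 for let-7 and 0.414 to 1.000 for miR-30.

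The planned edgeR and DESeq2 fits and the blocked edgeR fit were not run, because the deposited values list no single reads and were not taken as counts. At these depths, with noise independent between miRNAs and with larger changes in the same simulations, simulated log2 folds of 1 were called in 37.5% of cases.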

Other observations

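The tests of blood cells, of sequencing depth, of zeros and of the miR-132 and miR-212 arms, and the use of the components in weighing a GC trend in the libraries numbered 3, were chosen after the values they concern had been seen. The 4 arms of the miR-132 and miR-212 hairpins, which lie in introns of the same gene in GENCODE M21 (GRCm38) and are known to be induced by neuronal activity, were all higher in SE-BDEV, with a mean log2 difference of 0.88. miR-132-5p was at 1.06, miR-212-5p at 0.95, miR-212-3p at 0.80 and miR-132-3p at 0.71. A hypothesis is that the arms of this locus rose together. It stays untested here, because the arms were picked after they were seen to be higher: the directional test of fry (p = 0.0379, 0.0634 with the replicate block) and an exact permutation test of their mean (p = 0.1, the smallest it allows) restate that observation. Removing a GC trend left 118% of their mean difference, which argues against that trend as the source. In the main comparison no arm passed limma over all miRNAs, and miR-132-5p passed under 4 of 24 alternatives (adjusted p from 0.0408 to 0.723). These were array weights and 3 runs with the block, and it did not pass with the block over miRNAs above 0 in all libraries.

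For miR-155-5p, miR-21a-5p and miR-142a-5p, the first explanation weighed was GC content, since log2 fold changes correlated with hairpin GC across miRNAs (rho = -0.36, or -0.15 without CON-BDEV 1, and miRNAs are not independent replicates). With the trend removed all 3 stayed past the threshold and kept at least 82.3% of their log2 fold change. With GC taken from the side of the hairpin that holds the arm, miR-142a-5p kept 78.8% (1.46 ± 0.32, SE, limma adjusted p = 0.0244), below the bound of 80% set beforehand, but remained called. Whole blood would bring its abundant miRNAs, and the 3 tested members of the blood list had a median log2 difference of -0.0748, with the highest at 0.51, below the 1.85 of miR-142a-5p. As miR-451a and miR-144-3p of that list were at 0 in all libraries, these 3 members cannot decide on blood as a whole. miR-223-3p, a myeloid miRNA under the filter, was at 3.41, 2.58 and 0 RPM in CON-BDEV 1, 2 and 3 and at 6.18, 7.21 and 4.30 RPM in SE-BDEV, so entry of myeloid blood cells stays open. Of the 10 splits of the 6 libraries into 3 and 3, only the real split, 1 of the 10, gave 3 miRNAs and the highest other gave 0, and 10 splits are too few for a share under 0.05. With the block, the 4 splits that part all pairs gave 10 for the real split and at most 0 for the others. More microglial or inflammatory miRNA in the vesicles remains an open hypothesis, and other sources of these miRNAs were not tested.

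Both libraries numbered 3 lay apart on the first component. This fits a single miRNA: without miR-24-3p the first component, then with 38.0% of the variance, no longer set them apart. miR-24-3p was also the 1 miRNA past the threshold for these libraries against the rest (limma adjusted p = 9.60e-13). That p restates the observation, because the grouping was taken from the component that includes this miRNA. A difference in depth is argued against, since their mean of 6663955 reads lay between the 4400167 and 9391887 of the others. No list passed for these libraries, with a lowest adjusted p of 0.558, which met the bound set beforehand against another mix of cells or regions, although a high p does not show an equal mix. The correlation of their difference with hairpin GC was rho = -0.25, between the bounds set, so a part of a GC trend cannot be told apart. The first component without miR-24-3p does not decide this, since CON-BDEV 1 lay farthest out on it (-11.22) and a weaker trend need not show there. No biological explanation was tested.

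Some miRNAs were listed at exactly 0 in libraries where others had many reads. let-7b-3p was at 0 in CON-BDEV 1 and SE-BDEV 3 beside 89 to 149 reads elsewhere, and miR-24-3p at 0 beside 23312 and 21113 reads. For miR-24-3p the lower library above 0 implied at least 13764 reads in each of the 4 at 0, which argues against counting noise there. The other 6 tested miRNAs with zeros, each above 0 in at least 4 libraries, had 9 zeros where the lowest library above 0 implied at least 42 reads. With as many reads per molecule as their largest ratio of variance to mean allowed, 33.0, chance gave 0.889 zeros at these 9 places. That sum took in only places already seen to be 0, in miRNAs picked for their zeros. It is not the number of zeros expected over the tested miRNAs, so counting noise cannot be told apart for these 6. Over all miRNAs 592 zeros fell where 10 or more reads were implied, against 0.00192 expected at those same places by Poisson counting of single molecules. Of these 111 were of miRNAs above 0 in 3 or more libraries and 323 of miRNAs above 0 in 1 library alone, and 10 were at 100 or more reads. Since reads were not known to be collapsed by molecular identifier, counting noise cannot be told apart for the miRNAs under the filter either. Among the 17 miRNAs listed at 0 in exactly 3 libraries with all 3 zeros of this kind, 5.88% had them on 1 whole group, where chance gives 10%, and with an upper exact 95% limit of 28.7% a difference between the groups cannot be told apart. In the authors' deposited table miR-6983-5p rests on 3 such zeros, while 1 of the 3 zeros of miR-1247-5p was of this kind.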
